A study of Mus musculus with 10 samples.

How the data were processed

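Total RNA from the ileum of 5 iPGC-1β and 5 wild-type mice was extracted with Qiazol, checked on a Bio-Rad Experion, labelled with biotin and hybridised to Illumina arrays, per the labels' protocols. GenomeStudio is named in the submitters' processing notes, with no version. The deposited table per probe holds, per the file headers, the average signal, an intensity on a linear scale, and a detection p-value for each array, for 25697 probes with 18138 gene symbols. A second deposited table holds the authors' processed intensity values of the same arrays. How these were made is not given in the sources used here; read from the values, they are linear, share a median of 141.7 on every array and keep the order of the probes within each array (rank correlation of 1.00), as quantile normalization without background subtraction gives. Every column was matched to a sample by its title or accession, and 0 columns of sample values were left unused.

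The intensities were background-corrected with normexp, its negative-control mean and variance inferred from the detection p-values, with an offset of 16, then quantile-normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). A probe was kept where its detection p was under 0.05 on at least 5 of the 10 arrays, which left 12349 probes. For each symbol the kept probe with the highest mean over all arrays stood for the gene, giving 9365 genes; 2202 symbols had several kept probes. Of 623 other kept probes of called genes, 591 (94.9%) differed in the same direction as the chosen probe, and 1 was itself called in the opposite direction. Gene names are those of the array's design. Of the 18138 symbols 14307 are current in the reference table of the mouse assembly GRCm38.p6 and 2906 were matched through a synonym of 1 gene only; 925 were not matched and kept as they are. No coordinates of that assembly were used except the order of genes.

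The groups were taken from the genotype label. Replicate numbers were given in order within each group, do not pair arrays across groups and only name arrays. The series calls the wild-type mice littermates, but no litter, sex, slide or pooling is given in the sources used here, so p-values measure the spread between these samples. Correlations between arrays over the tested genes lay between 0.962 and 0.987 within the wild-type group, between 0.959 and 0.982 within the iPGC-1β group and between 0.923 and 0.969 across groups, and 0 pairs of arrays held identical values. The first principal component, with 38.2% of the variance, parted the groups; wild-type replicate 5 and iPGC-1β replicate 3 lay at opposite ends of the second, with 19.3%.

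The groups were compared with limma (lmFit and eBayes, no covariates), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fold changes are iPGC-1β over wild-type. Where a probe was not above background on any array of a group, the change is given as at least N-fold, against the higher of the array's lowest detected value and the probe's own. A total of 49 gene lists of pathways, cell types and controls was fixed before the data were examined. The 46 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list and with fry, which asks whether a list's genes move one way and does not compare them with other genes. The mean of each list per array was also compared with a two-sided exact permutation test over all 252 relabelings, whose smallest possible p is 0.00794, adjusted over the same lists. Named in the text are every probe of Ppargc1b and Ppargc1a, the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, and up to 4 members with the smallest unadjusted p of each list described, a rule also fixed before the data were examined; some members it picks are not used here.

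The pipeline was tested on simulated data with the means and spreads of the 9365 genes and 200 changed genes. At a log2 change of 1.5 it recovered 92.5% of them with 7.96% of calls false, at 1 it recovered 82.0% with 5.75% false, and at 0.5 it recovered 0%. Of 40 unchanged lists it called 0 at each size. In those simulations genes vary independently, unlike real genes of one tissue. With only 200 changed genes the adjusted threshold is also stricter than in the data, where 1619 genes were called. The recovered shares are therefore not those of the real comparison.

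Alternatives were no background correction, median centring or cyclic loess in place of quantile normalization, the authors' processed values, no filter or a stricter one (detection p under 0.01 on all 10 arrays), all kept probes, an adjusted p under 0.10, a minimum of 1.5-fold, a variance trend with robust fitting, array weights, each array left out, and the smooth muscle or B cell mean as a covariate. The enterocyte or T cell mean as a covariate, and leaving out wild-type replicate 5 and iPGC-1β replicate 3 together, were added after the data were seen. A covariate for sex was planned only if the difference between Xist and the Y-linked probes spanned more than 2 on the log2 scale, and it spanned 1.20. A block for the slide was planned only if slides were named, which they are not in the sources used here. Genes encoded by mitochondrial DNA, mast cell markers and sex-linked genes had fewer than 5 measured members and were not tested as lists.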

Results

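Gene expression was measured in the ileum, the last part of the small intestine, of 5 mice labelled iPGC-1β and 5 wild-type mice that the series describes as littermates. All were of the FVB/N strain and 3 to 4 months old. PGC-1β is the product of Ppargc1b, a transcriptional coactivator known to raise genes of mitochondrial respiration. The name iPGC-1β is used in this field for mice that overexpress it in the intestinal epithelium, which the labels themselves do not spell out. The question was which genes of the ileum differ between these mice and their wild-type littermates. Each array gave a signal for 25697 probes, of which between 12370 and 12771 per array lay above background at a detection p under 0.05. After a filter on dim probes, 9365 genes were tested. The number of arrays, 5 per group, limits the precision of every value given here.

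The Ppargc1b probe was not higher on the arrays labelled iPGC-1β. Its log2 intensity was 7.70 ± 0.41 (SD, n = 5) there and 8.32 ± 0.22 (SD, n = 5) on the wild-type arrays, a log2 difference of -0.61 ± 0.19 (SE), with limma's adjusted p = 0.0452 and a two-sided exact permutation p = 0.0317. Ppargc1a, which encodes the related coactivator PGC-1α, was lower too, at 7.08 ± 0.43 against 8.04 ± 0.36 (SD, n = 5 each), a log2 difference of -0.96 ± 0.22 (SE) with limma's adjusted p = 0.0106 and a two-sided exact permutation p = 0.0159. In both genes the groups overlapped by at least 1 array. Each gene has 1 probe in the deposited table, its position in the transcript is not given in the sources used here, and a probe outside the part carried by a transgene does not read that transgene. So these probes do not check the labels, and every direction below rests on the arrays as labelled. The call for Ppargc1b was lost, with the difference still negative, under median centring (adjusted p = 0.0550), without the filter on dim probes, and when any 1 of wild-type replicates 1, 2, 4 and 5 and iPGC-1β replicates 1, 3 and 4 was left out (limma's adjusted p between 0.0756 and 0.0998). The call for Ppargc1a was lost with the mean of the enterocyte markers as a covariate, chosen after the data were seen (-0.62, adjusted p = 0.210). With that covariate Ppargc1b lay at -0.98 and kept its call (limma's adjusted p = 0.0281).

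**Figure D1:**
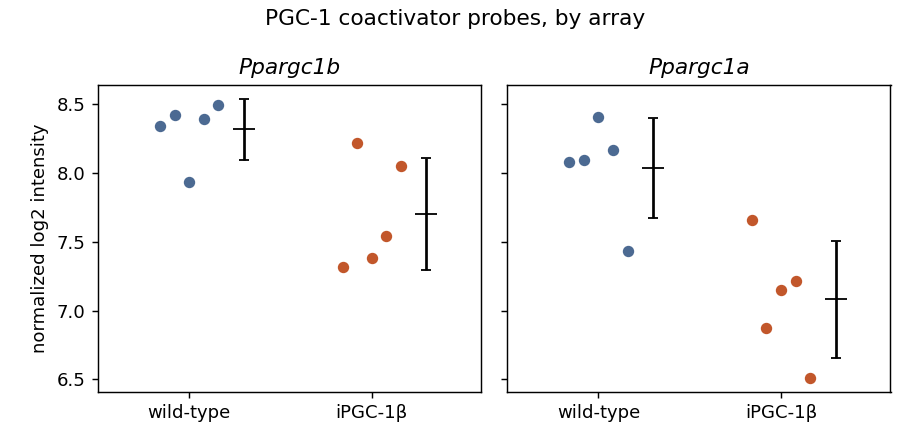
Normalized log2 intensity (vertical axis) of the probes for Ppargc1b and Ppargc1a on each of the 5 wild-type and 5 iPGC-1β arrays (points), with the mean and SD of each group (black). Group means lie at 8.32 and 7.70 for Ppargc1b and at 8.04 and 7.08 for Ppargc1a, wild-type first.

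Across the ileum, 9365 genes were tested with limma at an adjusted p under 0.05. Of these, 925 (9.88%) were higher and 694 (7.41%) lower on the iPGC-1β arrays. The rises were the larger changes: 268 of the higher genes and 92 of the lower genes differed at least 2-fold. All 5 iPGC-1β arrays lay beyond all 5 wild-type arrays for 737 of the higher and 424 of the lower genes. Among all tested genes 1337 were separated in this way, where chance gives 0.794% of genes. Without any 1 of wild-type replicates 1 to 4 the number of lower genes lay between 421 and 458. With the same enterocyte covariate 750 genes were higher and 616 lower, among them 592 of the 925 higher and 226 of the 694 lower genes. The covariate itself was lower on the iPGC-1β arrays (mean 10.65 against 11.21), so it takes up part of the group difference.

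The gene with the largest rise was 0610012D14Rik, now named Aspdh. Its brighter probe was not above background on any wild-type array and read at least 15.5-fold higher on the iPGC-1β arrays after background correction (limma's adjusted p = 9.9e-06), while its log2 change was 2.19 without that correction. A second probe of the gene differed by 2.65 on the log2 scale, and it took the place of the first when any 1 iPGC-1β array was left out, with a lowest value of 2.47 for 0610012D14Rik. Next came B230317C12Rik, now Dipk1b, at 10.8-fold, and Pcolce, which encodes an enhancer of procollagen processing, at 10.0-fold. Ttc36 rose 6.72-fold, and Hcn2, a cation channel gene known from heart and brain, rose 6.46-fold. Sirt3, which encodes the main mitochondrial protein deacetylase, rose 5.63-fold, from a log2 intensity of 8.20 ± 0.18 to 10.69 ± 0.18 (SD, n = 5 each), with the smallest adjusted p of all genes, 1.4e-06 by limma. The other genes of the 12 with the largest rises and separated groups were BC067047 at 5.87-fold, Acy3 at 4.50-fold, Rasl2-9 at 4.42-fold, 9530058B02Rik (now Mcrip2) at 4.41-fold, Ccdc114 at 4.21-fold and Oplah, which encodes 5-oxoprolinase of glutathione turnover, at 4.12-fold. The sizes of dim genes depend on the background correction: without it the calls were kept, and the log2 changes were 1.66 for B230317C12Rik, 1.84 for Pcolce, 1.504 for Hcn2, 1.16 for BC067047, 0.87 for Rasl2-9, 1.04 for Ccdc114 and 1.13 for Oplah. B230317C12Rik and Pcolce then ranked below Ttc36 and Sirt3, whose log2 changes were at least 2.11 and 2.09 under every alternative.

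The gene with the largest fall was Susd2, from 8.65 ± 0.50 to 5.89 ± 0.28 (log2 intensity, SD, n = 5 each), a log2 change of -2.75 ± 0.23 (SE). Angptl4, which encodes an inhibitor of lipoprotein lipase, changed by -2.62 ± 0.41 (SE). Acta1, skeletal muscle actin, changed by -2.51, Mfsd7c (now Flvcr2) by -2.08, Lxn, a carboxypeptidase inhibitor gene, by -2.08, the keratin gene Krt84 by -2.04 and AU042651 (now Slc25a48) by -1.86. Krt84 was above background on 1 and AU042651 on 2 iPGC-1β arrays. Phlda1 changed by -1.82 and Dusp6, a phosphatase gene that restrains ERK kinases, by -1.54. Aldh4a1, of proline breakdown, changed by -1.66, Cdr2 by -1.60 and Bach1, a heme-binding repressor gene, by -1.51. These 12 genes had adjusted p-values between 9.9e-06 and 0.0238 in limma. Without background correction the changes of the dimmer ones were smaller and still called, at -1.53 for Susd2, -1.37 for Acta1, -0.94 for Mfsd7c, -0.76 for Krt84 and -0.67 for AU042651. Lxn, at -1.74 or lower under every alternative, was then a larger fall than Susd2. The calls of Phlda1 and Aldh4a1 were lost without wild-type replicate 3 (adjusted p = 0.0602 and 0.0596) or iPGC-1β replicate 1 (0.0520 and 0.0526), that of Aldh4a1 without wild-type replicate 4 (0.0515) and that of Phlda1 without iPGC-1β replicate 3 (0.0526). Both were also lost without the filter (0.0519 and 0.0528), with trend and robust variance (0.0591 and 0.0584) and with the T cell covariate (0.0534 and 0.124). With the enterocyte covariate, the calls of Phlda1 (0.448), of Aldh4a1 (0.190), of Angptl4 (adjusted p = 0.0515) and of Cdr2 (0.0563) were lost.

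**Figure D2:**
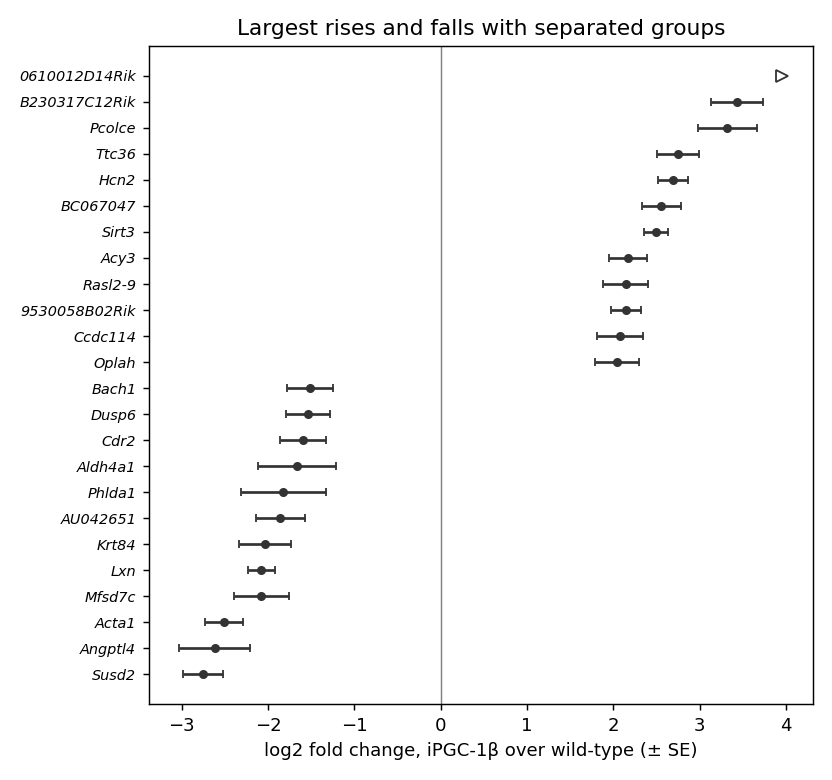
Log2 fold change of iPGC-1β over wild-type arrays (horizontal axis) with its SE for the 12 genes with the largest rises and the 12 with the largest falls among genes with an adjusted p under 0.05 and no overlap of the groups, 5 arrays each. The open triangle is the lower bound of 3.96 for 0610012D14Rik, not above background on wild-type arrays; the other rises run from 2.04 for Oplah to 3.43 for B230317C12Rik and falls from -1.51 for Bach1 to -2.75 for Susd2.

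Genes of the respiratory chain rose together. Of 68 measured genes for subunits of complexes I to V and cytochrome c, 50 rose, 0 fell and 18 did not pass the test. Adjusted over the list alone, 57 rose. The median log2 change of the list was 0.71. Ndufs3 of complex I rose 2.22-fold and Ndufb8 2.18-fold, and Sdhb of complex II rose 2.22-fold (limma's adjusted p between 4.6e-05 and 5.9e-05). The list was higher than the other genes by camera with a preset correlation (adjusted p = 3.7e-30), and adjusted p = 0.230 with an estimated correlation. The mean of the list was higher on all 5 iPGC-1β arrays than on any wild-type array (two-sided exact permutation p = 0.00794, the smallest that 5 against 5 can give, and 0.0365 adjusted over 46 lists).

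Transcripts of enzymes of the tricarboxylic acid cycle and of pyruvate dehydrogenase rose too. Of 21 measured genes 18 rose and 0 fell, and adjusted over the list alone 18 rose, with a median log2 change of 0.97. Idh3a, a subunit of isocitrate dehydrogenase, rose 2.81-fold and the pyruvate dehydrogenase gene Dlat 2.57-fold, or 0.75 on the log2 scale without background correction (limma's adjusted p between 4.0e-05 and 5.6e-05). Camera gave an adjusted p = 2.2e-17, and an adjusted p = 0.128 with an estimated correlation. The groups did not overlap in the mean of the list (exact permutation p = 0.00794, adjusted 0.0365).

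Transcripts of the machinery that builds mitochondria were higher as well. Of 69 measured genes for mitochondrial ribosomal proteins 38 rose and 0 fell (45 and 0 adjusted over the list alone), with a median log2 change of 0.51. Mrpl55 rose 2.96-fold and Mrps5 2.91-fold. Of 31 measured genes of mitochondrial protein import, chaperones, fission and fusion 19 rose and 0 fell (20 and 0 adjusted over the list alone), with a median of 0.60; Slc25a4, the heart and muscle form of the ADP/ATP carrier, rose 3.86-fold from a probe above background on 1 wild-type array, with a log2 change of 0.67 without background correction, and Chchd4 rose 2.37-fold. Among 22 measured regulators of mitochondrial biogenesis and of mitochondrial DNA 7 rose and 2 fell (8 and 2 adjusted over the list alone). Peo1 (now Twnk), the mitochondrial DNA helicase gene, above background on 2 wild-type arrays, rose 2.34-fold (0.37 on the log2 scale without background correction), Tfam, which encodes the packaging factor of mitochondrial DNA, rose 1.88-fold, and the transcription factor gene Tfb2m rose 1.85-fold. Camera gave adjusted p-values of 3.1e-18 for the ribosome, 5.0e-14 for import and 0.00499 for the regulators. With an estimated correlation the adjusted p-values were 0.466, 0.0870 and 0.466. In all 3 lists the groups did not overlap in the mean (exact permutation p = 0.00794 each, adjusted 0.0365). Genes of the mitochondrial DNA itself were not analysed here.

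Fatty acid oxidation went partly along. Of 31 measured genes 11 rose and 2 fell (12 and 3 adjusted over the list alone), with a median log2 change of 0.31. Bdh1, of ketone body metabolism, rose 3.55-fold, the very-long-chain dehydrogenase gene Acadvl 2.70-fold and Echs1 2.49-fold. Acat1, above background on 2 wild-type arrays, rose 2.45-fold (0.42 on the log2 scale without background correction). By camera the list was higher with an adjusted p = 7.6e-04, and an adjusted p = 0.470 with an estimated correlation; the groups overlapped in the mean of the list (exact permutation p = 0.0714, adjusted 0.126). The mean log2 change of the list was 0.27, and 0.17 without wild-type replicate 5, 0.18 without iPGC-1β replicate 3, and 0.077 without both, an omission chosen after the data were seen, where camera's adjusted p was 0.0983. With the enterocyte covariate it was 0.62 (adjusted p = 2.1e-07), with the B cell covariate 0.17 (0.00910), and with the T cell covariate 0.084 (0.0707).

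Genes of antioxidant enzymes split into a part that rose and a larger part near 0. Of 32 measured genes 8 rose and 0 fell, also when adjusted over the list alone, and the median log2 change was 0.0031. Those that rose include several that act in mitochondria: Sod2, the mitochondrial superoxide dismutase gene, rose 2.10-fold and the thioredoxin gene Txn2 2.10-fold, while Prdx2, a cytosolic peroxiredoxin gene, rose 2.22-fold and Glrx5, of iron-sulfur cluster assembly, 2.00-fold (limma's adjusted p between 1.1e-04 and 2.7e-04). Camera did not call the list (adjusted p = 0.0663), while its mean, 0.23 higher, was separated between the groups (exact permutation p = 0.00794, adjusted 0.0365).

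Some glycolytic genes rose: 8 of 24 measured, with 0 falling (8 and 2 adjusted over the list alone) and a median log2 change of 0.18. Hk1, a hexokinase gene above background on 1 wild-type array, rose 3.76-fold (0.69 on the log2 scale without background correction), Pgam1 2.81-fold, Aldoa 2.04-fold and Tpi1 1.95-fold. Camera gave an adjusted p = 0.00784, and an adjusted p = 0.470 with an estimated correlation; the groups did not overlap in the mean of the list (exact permutation p = 0.00794, adjusted 0.0365). Camera's call was lost without wild-type replicate 5 (adjusted p = 0.0538) and without that array and iPGC-1β replicate 3 together (0.118). Its mean log2 change of 0.36 became 0.71 with the enterocyte covariate (9.4e-06) and 0.23 with the T cell covariate, where the call was lost (0.09999).

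**Figure D3:**
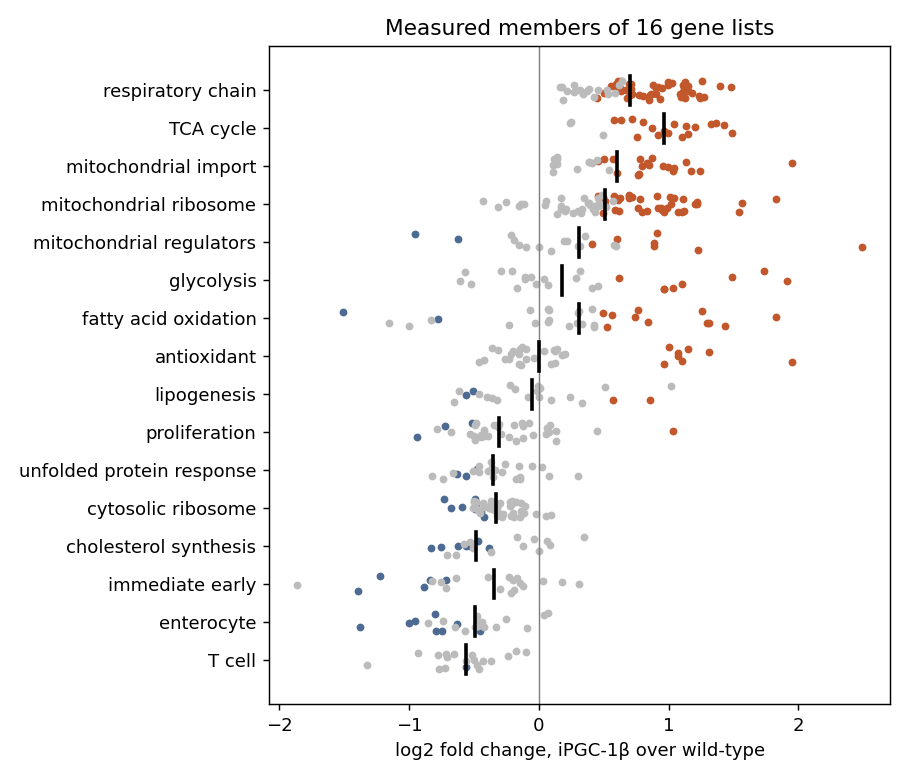
Log2 fold change of iPGC-1β over wild-type arrays (horizontal axis) for each measured gene of 16 lists fixed before the data were examined. Orange points rose and blue points fell at an adjusted p under 0.05, grey points did not pass, and black bars are medians, which run from 0.97 for the TCA cycle to -0.56 for the T cell markers.

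Lipid synthesis gave no common shift. Of 22 measured genes of fatty acid and triglyceride synthesis 2 rose and 2 fell (2 and 3 adjusted over the list alone). Acss2 rose 1.49-fold and Scd2 1.81-fold, Slc25a1 changed by -0.50 and Fads1 by -0.56 on the log2 scale. The calls of Scd2, Fads1 and Slc25a1 are weak, kept under 11, 13 and 15 of 24 alternatives, and the log2 change of Scd2 lay between 0.39 and 1.14. The median was -0.05 and camera's adjusted p = 0.559. Cholesterol synthesis was lower: 7 of 20 measured genes fell and 0 rose (10 and 1 adjusted over the list alone), with a median of -0.49. Hsd17b7 changed by -0.83, the squalene epoxidase gene Sqle by -0.75 and Idi1, whose call was kept under 16 of 24 alternatives, by -0.47. For this list camera gave an adjusted p = 0.00293, and an adjusted p = 0.477 with an estimated correlation; the exact permutation p of the mean was 0.0159, adjusted 0.0522.

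Markers of absorptive enterocytes were lower on the iPGC-1β arrays. Of 23 measured markers 8 fell and 0 rose (10 and 0 adjusted over the list alone), with a median log2 change of -0.49. The brush border peptidase genes Mep1b and Anpep changed by -0.79 and -0.80, the peptide transporter gene Slc15a1, above background on 2 iPGC-1β arrays, by -0.95 (-0.28 without background correction) and the amino acid transporter gene Slc7a9 by -0.75. The markers were lower by camera with an adjusted p = 1.4e-05, and an adjusted p = 0.470 with an estimated correlation; the exact permutation p of the mean was 0.0238, adjusted 0.0576. Wild-type replicate 5 had an enterocyte mean of 10.75, against 11.19 to 11.47 on the other wild-type arrays.

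Lists tied to enterocytes went the same way. Of 21 measured genes of lipid uptake and lipoprotein assembly 4 fell and 0 rose, also when adjusted over the list alone: the lipid droplet gene M6prbp1 (now Plin3) changed by -1.26, the fatty acid transporter gene Slc27a4 by -1.25, Soat2 by -1.23 and Mttp by -0.90. Of 13 measured genes of ileal bile acid handling 3 fell and 0 rose, also when adjusted over the list alone: Fgf15, the hormone gene that ileal bile acids induce, changed by -1.79 (-0.82 without background correction), its activating receptor gene Nr1h4 (FXR) by -0.64 and the bile acid exporter gene Ostb (now Slc51b) by -0.81. The calls of Nr1h4 and Ostb were kept under 20 and 12 of 24 alternatives. Of 10 measured markers of the distal small intestine 4 fell and 0 rose, also when adjusted over the list alone, and all of them (Fgf15, Ostb, Mttp and Mep1b) are also members of the lists already described. Camera gave an adjusted p = 0.04996 for each of these 3 lists, and adjusted p-values of 0.677, 0.470 and 0.466 with an estimated correlation. Single arrays decide these calls. Without iPGC-1β replicate 2 the adjusted p-values were 0.227, 0.111 and 0.117, without wild-type replicate 3 they were 0.134, 0.0699 and 0.0611, and without wild-type replicate 4 they were 0.0745, 0.0597 and 0.0745. The lipid uptake call was also lost without iPGC-1β replicate 1 (0.0669) or 5 (0.0553), and the other calls without wild-type replicate 2 (0.0726 and 0.0766). Under cyclic loess the adjusted p-values were 0.0658, 0.0561 and 0.0658. The lipid uptake call was also lost with array weights (0.0594) and fry (0.138), the bile acid call without background correction (0.0601), with the authors' processed values (0.0551) and with the stricter filter (0.147), and the distal marker call with the stricter filter (0.106) and array weights (0.0520). With the enterocyte mean as a covariate the lipid uptake list turned to 0.18 (adjusted p = 0.213). The mean of the bile acid list went from -0.56 to -0.11 (0.793) and that of the distal markers from -0.46 to -0.051 (0.522). The covariate was itself lower on the iPGC-1β arrays, and it holds Mep1b, which is also a distal marker. Part of these changes can therefore arise by construction. Without that covariate, markers of the proximal segment and of the colon had means of -0.42 and -0.59. Camera did not call either (adjusted p = 0.0667 and 0.0935).

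Transcripts of cytosolic ribosomal proteins were lower. Of 49 measured genes 8 fell and 0 rose (10 and 0 adjusted over the list alone), with a median of -0.33. Rps26 changed by -0.73, Rps19 by -0.68 and Rpl13a by -0.59; a second probe of Rps19 differed by -0.15. The mean of the list, -0.32, became -0.55 with the enterocyte covariate (adjusted p = 4.3e-11) and -0.20 with the T cell covariate (0.00107). The list was lower by camera with an adjusted p = 3.5e-07, and an adjusted p = 0.470 with an estimated correlation; the groups did not overlap in the mean of the list (exact permutation p = 0.00794, adjusted 0.0365). The unfolded protein response list had 3 of 24 genes lower and 0 higher, and 0 of either adjusted over the list alone, with a median of -0.36. Xbp1 changed by -0.48, Dnajb9 by -0.56 and Pdia6 by -0.63, calls kept under 17, 14 and 9 of 24 alternatives, with Dnajb9 between -0.70 and -0.23 and Pdia6 between -1.11 and -0.27. For the list camera gave an adjusted p = 0.00512, and an adjusted p = 0.466 with an estimated correlation; the mean was separated between the groups (exact permutation p = 0.00794, adjusted 0.0365). Of 22 measured immediate early genes, which respond to handling and stress of tissue, 5 fell and 0 rose (7 and 0 adjusted over the list alone). Socs3 changed by -1.39, Klf6 by -0.89, Klf4 by -0.84 and Rhob, whose call was kept under 14 of 24 alternatives, by -0.72; camera gave an adjusted p = 0.00762, and an adjusted p = 0.470 with an estimated correlation (exact permutation p = 0.0159, adjusted 0.0522). With the enterocyte covariate the mean log2 change of these genes went from -0.51 to -0.22 (camera's adjusted p = 0.441).

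Markers of T and B cells differed between single arrays. Of 19 measured T cell markers 1 fell, Klrd1 by -0.56 with a call kept under 13 of 23 alternatives, and 0 passed when adjusted over the list alone; Cd8b1 at -0.93, Nkg7 at -0.78 and Ccl5 at -1.32 did not pass. The mean log2 change was -0.58, with camera's adjusted p = 0.00673 and an adjusted p = 0.634 with an estimated correlation (exact permutation p = 0.0635, adjusted 0.117). Without iPGC-1β replicate 3 it was -0.26 (adjusted p = 0.0440): that array had a T cell mean of 5.67, against 7.07 to 7.41 on the other iPGC-1β arrays. The call was lost without that array and wild-type replicate 5 together (-0.16, adjusted p = 0.205), with the stricter filter (0.0786), with array weights (0.0520) and with fry (0.204), and the mean was -0.31 without background correction (0.0111), -0.33 with the authors' processed values (0.0102) and -1.15 with the enterocyte covariate (3.4e-05). B cell markers did not pass, with 0 of 14 called and camera's adjusted p = 0.143; wild-type replicate 5 stood highest at 7.70. The antimicrobial and inflammatory list had 2 of 15 genes lower and 0 higher, also when adjusted over the list alone, with Lcn2 at -1.04 and Il18 at -1.18; camera gave an adjusted p = 0.04996, and an adjusted p = 0.470 with an estimated correlation. That call was lost without wild-type replicate 3 (0.0528) or 5 (0.0816) or iPGC-1β replicate 3 (0.0735) or 4 (0.0783), and under cyclic loess (0.0658). It was also lost with the stricter filter (0.0786), array weights (0.0867) and the B cell covariate (0.0903), without background correction (-0.29, 0.0562), with the authors' processed values (-0.30, 0.0547), with the T cell covariate (-0.22, 0.233) and without wild-type replicate 5 and iPGC-1β replicate 3 together (-0.28, 0.147). With the enterocyte covariate the mean of -0.47 became -0.91 (0.00486), and without the filter -0.29 (0.0129). The proliferation list had 3 of 35 genes lower (Ccnd2 at -0.94, Cdt1 at -0.51 and Plk1 at -0.73, the last 2 called under 14 of 24 alternatives) and 1 higher (Gmnn, whose probe was not above background on any wild-type array), and 2 and 1 adjusted over the list alone; camera gave an adjusted p = 0.0404, and an adjusted p = 0.768 with an estimated correlation. Its mean of -0.25 became -0.12 without wild-type replicate 5 (adjusted p = 0.406), -0.18 without iPGC-1β replicate 3 (0.0984), -0.23 without wild-type replicate 1 (0.0553) and -0.37 without iPGC-1β replicate 2 (0.00247). It was -0.76 with the enterocyte covariate (4.5e-10), -0.037 with the T cell covariate (0.804), -0.11 with the B cell covariate (0.281), -0.17 with array weights (0.163) and -0.047 without wild-type replicate 5 and iPGC-1β replicate 3 together (0.810). The call was also lost with the smooth muscle covariate (0.0504) and with fry (0.368).

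**Figure D4:**
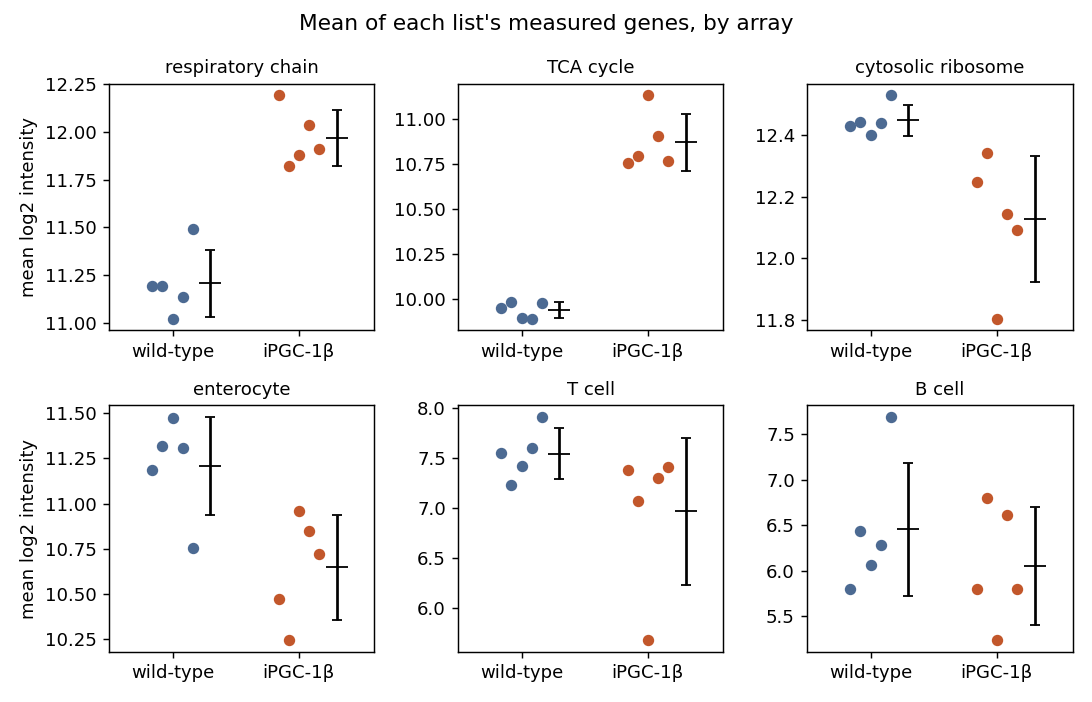
Mean normalized log2 intensity (vertical axis, a separate scale per panel) of the measured genes of 6 lists on each of the 5 wild-type and 5 iPGC-1β arrays (points), with the mean and SD of each group (black). The respiratory chain, TCA cycle and cytosolic ribosome panels show no overlap of the groups, and in the T cell panel iPGC-1β replicate 3 lies at 5.67.

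In all, camera with the preset correlation called 7 lists higher and 11 lower among 46 tested, all of them described above, while the antioxidant, lipid synthesis and B cell lists were not called. Counting either direction, 79 and 32 of 100 splits of the arrays, the real one included, gave at least 7 and at least 11 lists. With an estimated correlation camera called 0 of the lists, fry kept 15 of them, and the exact permutation of list means called 10 of the 46 lists, among them the goblet cell markers, with 3 of 17 genes lower and a mean log2 change of -0.23. Endothelial markers had 4 of 20 genes higher, with Flt1 at 0.92 (camera's adjusted p = 0.0577). Smooth muscle markers had 0 of 22 called (camera's adjusted p = 0.371). Markers of fibroblasts, enteric neurons, Paneth cells and crypt stem cells were not called by camera.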

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

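The tests on probe brightness, enterocyte share, exchanged labels and probe position, and the joint omission of 2 arrays, were chosen only after the results they bear on were seen. Each of 144 sets of 5 arrays, over the list means, the PGC-1 coactivator probes and the genes with the largest changes in each group, was searched for 1 array far from the other 4. That search singles out about 1 in 20 sets by chance, 7.2 here, and it found 17.

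Wild-type replicate 5 and iPGC-1β replicate 3 account for 10 of the 17. Wild-type replicate 5 differed from the mean of the other 4 wild-type arrays by -0.52 on the log2 scale in the fatty acid oxidation list, -0.39 in the glycolysis list, 0.37 in the proteasome list, -1.12 in the Paneth cell list, -0.50 for Acy3, -1.31 for Ccdc114 and -2.38 for Angptl4. In iPGC-1β replicate 3 the differences were -1.25 for MHC class II genes, -1.62 for T cell markers and -0.91 for myeloid markers. The other values were -0.28 in wild-type replicate 4 for cholesterol synthesis, -0.22 in iPGC-1β replicate 5 for endothelial markers, 0.24 and 1.26 in wild-type replicate 3 for pancreas and red cell markers, -0.48 in wild-type replicate 3 for Ppargc1b, and -0.74 for Ccdc114 and -0.62 for Susd2 in iPGC-1β replicate 1. Without wild-type replicate 5 and iPGC-1β replicate 3 together, 916 genes were higher and 779 lower, 760 and 507 of them shared with the full set of arrays.

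The first pattern weighed is the lower signal of Ppargc1b and Ppargc1a on arrays whose name points to more PGC-1β. Normalization is argued against: over the other 4 scalings and the non-normalized signal, the log2 difference of Ppargc1b nearest to 0 was -0.41. An exchange of the labels of the whole groups is argued against on the premise, from background knowledge, that PGC-1β raises respiratory chain genes, since the respiratory chain list was 0.76 higher on the iPGC-1β arrays with no overlap of the groups. Whether the probe reads a part of the transcript that a transgene lacks stays open, because the gene has only 1 probe and its position is not given; that, together with a lower level of the animal's own Ppargc1b and Ppargc1a, is a candidate explanation that these arrays cannot decide.

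The second is the rise of respiratory chain genes. The medians of 10000 random lists matched on brightness had an upper bound of 0.030, against 0.71, which argues against a trend with brightness. A larger share of enterocytes is argued against, as far as marker transcripts follow that share, by the enterocyte markers, which were not higher. Their median has an upper bootstrap bound of -0.46, but that bound resamples the 23 marker genes and not the animals. By arrays the groups overlapped in the mean of the markers (exact permutation p adjusted 0.0576). Without quantile normalization the mean rise was at least 0.67, under median centring and cyclic loess. The genotype may be the cause, as a hypothesis; slide and litter stay open, since neither is given in the sources used here. Sex, not given either, is argued against, since Ddx3y of the Y chromosome was above background on all 10 arrays and the difference between Xist and the Y-linked probes spanned 1.20 on the log2 scale, under the bound of 2 set in advance.

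Chance was tested with 100 splits of the 10 arrays into 5 and 5, the real one included. Only 1 of 100, the real split, gave as many as 925 higher genes, and only 1 gave as many as 694 lower genes; the highest of the other splits gave 7 genes in one direction. A random division of the arrays is thereby argued against for both counts, at a resolution of 1 in 100 splits. The other splits mix the genotypes, so the group difference adds to their spread and lowers their gene counts. A slide or litter that follows the genotype is not tested this way. For the counts of lists a random division is not argued against. A split and its mirror being one, each other split counts with its larger direction. So counted, 79 of 100 splits, the real one included, gave at least 7 lists in one direction and 32 gave at least 11. The largest count in another split was 15. The other splits are no clean measure of chance, since each holds unequal numbers of the genotypes on its sides and keeps part of the group difference. Genes of a list vary together between these arrays more than camera's preset correlation of 0.01 allows for, so the number of called lists carries no weight by itself. Single lists rest on their gene counts and on the permutation of their means, neither of which compares a list with other genes. Of all tested genes 9.88% were called higher and 7.41% lower. Far above that share lie the respiratory chain (50 of 68 higher) and the TCA cycle (18 of 21). The T cell (1 of 19 lower) and proliferation (3 of 35 lower) counts lie near it.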

How the results depend on the processing

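The enterocyte and T cell covariates and the joint omission of wild-type replicate 5 and iPGC-1β replicate 3 were chosen after seeing the data. The number of higher genes lay between 700 (at least 1.5-fold) and 1181 (adjusted p under 0.10) over all alternatives, and between 748 and 947 with 1 array left out. Lower genes numbered 421 to 792 with 1 array left out, with 449, 445, 421 and 458 without wild-type replicate 1, 2, 3 and 4; 1105 with array weights, 1077 at an adjusted p under 0.10 and 446 with the T cell covariate. The share of calls that were higher was 57.1%, and between 49.2% (median centring) and 58.2% (cyclic loess) under other scalings, and the median of all genes moved between -0.10 and -0.02. The cause was not tested for any of these shifts, except that the looser threshold admits more genes by construction.

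The lower Ppargc1b signal stayed negative under every alternative run, and was -0.98 with the enterocyte covariate, where it passed. It did not pass under median centring (-0.66), without the filter (-0.61, more genes tested), with the smooth muscle (-0.52), B cell (-0.52) or T cell (-0.50) covariate, or without both arrays (-0.49); with 1 array left out it lay between -0.74 and -0.52, and passed only without wild-type replicate 3 or iPGC-1β replicate 2 or 5. The cause was not tested.

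The mean shifts of the respiratory chain (0.76), TCA cycle (0.93) and fatty acid oxidation (0.27) lists kept their value and lost their call with an estimated correlation, where the number of lists called was 0 higher and 0 lower. Fatty acid oxidation also fell short with the T cell covariate (0.084) and without both arrays (0.077), and rose to 0.62 with the enterocyte covariate. That covariate also enlarged the glycolysis (0.71), T cell (-1.15), proliferation (-0.76), antimicrobial (-0.91) and cytosolic ribosome (-0.55) shifts and reduced that of the mitochondrial ribosome (0.36), all still called. The T cell covariate reduced the cytosolic ribosome shift (-0.20, still called) and ended the calls of glycolysis (0.23), proliferation (-0.037) and the antimicrobial list (-0.22). Antioxidant genes passed with all kept probes (0.24), with fry (0.23) and without iPGC-1β replicate 2 or 5, in a range of 0.21 to 0.27 with 1 array left out. Lipid synthesis, never called, turned to 0.069 with the enterocyte covariate and ranged from -0.077 to 0.013 with 1 array left out (0.013 without wild-type replicate 3). With the enterocyte covariate lipid uptake (0.18) and Nr1i3 (0.090), a member of the bile acid list that had not passed, also turned. Lists lower numbered 7 with cyclic loess, the stricter filter or array weights, 15 without the filter or with all kept probes, and 7 to 13 with 1 array left out. The cause was not tested.

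Of 99 genes picked by the naming rule other than Ppargc1b, 62 stayed on their side of the threshold under all 24 alternatives run for genes, where they were measured, and 32 lost their call under at least 1, most often Pdia6, Scd2, Ostb and Fads1. Without background correction, or with the authors' processed values, changes of dim probes were smaller. The slide block and the sex covariate were not run. Dim probes limit what can be seen: 0610012D14Rik was not above background on wild-type arrays with its brighter probe.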

Other observations

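All lists and tests in this part were chosen after the gene values were seen, so they describe these arrays and are not independent evidence. In mitochondrial groups outside the lists fixed in advance, or overlapping them in part, more genes rose than fell. Of 10 measured genes of coenzyme Q synthesis 5 rose and 0 fell, with Coq5 at 1.39, Coq6 at 1.34, Coq9 at 1.27 and Coq7 at 1.05 on the log2 scale. Of 21 genes of iron-sulfur cluster assembly and heme synthesis, 3 of them also in fixed lists, 11 rose and 0 fell, among them the mitochondrial carrier gene Slc25a39 at 1.76, Bola3 at 1.58 and the scaffold gene Iscu at 1.39. Of 25 genes of mitochondrial translation other than ribosomal proteins 9 rose and 0 fell, with Qrsl1 and Gfm1 at 1.68. Camera over 7 such lists gave adjusted p-values of 7.7e-06, 2.1e-06 and 1.6e-06 for these 3, and adjusted p = 0.0397, 0.0369 and 0.0487 with an estimated correlation. The adjustment here is over 7 lists and that of the fixed lists over 46, so the adjusted values do not compare. Unadjusted, camera with an estimated correlation gave p = 0.0113, 0.0053 and 0.0209 here. For the fixed TCA cycle and mitochondrial import lists it gave 0.0056 and 0.0019. Carriers of the Slc25 family, 6 of them in fixed lists, had 9 of 29 higher and 2 lower, with a median log2 change of 0.28 (camera's adjusted p = 3.2e-04, and 0.132 with an estimated correlation). Amino acid breakdown in mitochondria, with 2 genes in fixed lists, had 6 of 22 higher and 1 lower, with a median of 0.094 (0.0175, and 0.132).

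Part of a list of genes taken here as targets and feedback regulators of EGF receptor and ERK signalling was lower. Whether each gene of it answers to that signalling in the ileum was not tested. Of 13 measured genes 6 fell, 0 rose and 7 did not pass, with a median of -1.27, and 3 genes of the list are also in fixed lists. Among those that did not pass, Egr1 changed by -1.86 with a wild-type SD of 1.61, while Spry4 (0.23), Dusp4 (0.15) and Ier3 (-0.17) changed little. Phlda1, Dusp6 and Cdr2 were among the 12 largest falls, already seen when the list was made, so their fall lends it no support. The other genes that fell were the receptor ligand gene Areg at -1.62, Spry3 at -1.39 and the receptor gene Egfr at -0.60. For the list camera gave an adjusted p = 1.1e-04, and an adjusted p = 0.132 with an estimated correlation. With the enterocyte covariate the calls of Phlda1 (-0.79) and Cdr2 (-0.76) were lost. Targets of PPAR alpha did not move together: of 12 measured genes 2 rose, Retsat at 1.36 and Acadm at 0.56, and 2 fell, Angptl4 at -2.62 and Acot1 at -1.51. Counting genes that did not pass the filter on dim probes, 13 of this list are also in fixed lists, so it mostly regroups genes of those. The median was -0.02 and the mean -0.31, while camera gave the direction as up, with an adjusted p = 0.973.

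Genes that rose often lay beside each other, as Hcn2 (2.69) does between Bsg (0.86) and the mitochondrial RNA polymerase gene Polrmt (0.89), Ttc36 (2.75) beside Tmem25 (1.76), and Mrpl55 (1.56) beside Guk1 (1.82). The reference annotation placed 8846 of the tested genes (94.5%) in order. Of adjacent pairs 122 both rose, against 71 to 105 in the central range of 10000 shuffles (one-sided permutation p = 2.0e-04), which argues against chance placement. When pairs whose symbols share their first 3 letters were left out, 120 did (68 to 101 in shuffles). Pairs with such like symbols therefore do not account for the excess. Probe signal shared by neighbours with unlike symbols is not tested this way and stays open. Pairs 5 to 10 genes apart that both rose numbered 96 on average, and adjacent pairs that both fell numbered 54, within 37 to 62. Neighbours may share control elements, a hypothesis these values leave open. A chromosome segment of another strain cannot be told apart from chance here: at most 9 genes changed at least 1.5-fold among 20 consecutive genes, where shuffles gave 8 to 10.

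H2-Eb1 stood apart in the MHC class II list. It was higher by 1.49 ± 0.18 (SE) on the log2 scale, with limma's adjusted p = 1.7e-04 and no overlap of the groups, while H2-Ab1 (-0.76), H2-Aa (-0.34), Cd74 (-0.27) and H2-Oa (0.58) did not pass, and Ctss, which encodes cathepsin S, was lower by -0.50.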
